A study of Drosophila melanogaster with 24 samples.

How the data were processed

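Chromatin immunoprecipitation with sequencing (ChIP-seq) was done in Kc167, a Drosophila melanogaster cell line derived from embryos. The 24 libraries fell into 8 groups by treatment and antibody. Mock cells gave 2 libraries each for Su(Hw), Mod(mdg4)2.2, CP190 and each of 2 CLAMP antibodies, and 10 input libraries. Cells given double-stranded RNA (dsRNA) against Clamp gave 2 CLAMP libraries with the second antibody and 2 inputs. Per the labels' protocols, each culture received 5 ug of the RNA and was kept for 6 days. The CLAMP antibody that the labels call clamp is the first antibody below, and the one they call clamp-abcam is the second.

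The authors deposited 6 lists of peaks, 1 per antibody and treatment, without header lines and in the narrowPeak layout. The row names of the deposited lists carry the word pooled, so each list came from the libraries of a group together. Per the submitters' processing notes, the tools were cutadapt 1.8.1, Bowtie2 2.2.9, SAMtools 1.2, Picard and MACS2 2.1.0.20150731, with genome build dm6; their settings and the peak threshold are not given in the sources used here. The fold enrichment deposited for each peak is a ratio of ChIP signal to background at the summit, as MACS2 writes it in this layout. The score in the deposited lists is 10 times the -log10 of the q-value rounded down, which was tested on every row. The deposited -log10 p and -log10 q of each peak are MACS2 values, of which only -log10 q was used, and the summit is deposited as an offset in bases from the peak start. Read numbers are not given in the sources used here, so the depth of each library is unknown. A missing peak therefore means that none passed the authors' threshold, and fold enrichments are not compared as amounts between lists.

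Peaks on chromosome arms 2L, 2R, 3L, 3R, 4 and X were used. No peaks of a list touched, so merging changed nothing. Gene names and positions came from a RefSeq gene table of the same assembly (Release 6 plus ISO1 MT), with 17673 genes on these arms. That table holds gene starts and ends but no strand, exon or sequence. For this reason the planned distance to transcription starts became the distance to either end of a gene, the planned exon and intron classes were not made, and the planned motif search at summits was not run. The length of an arm was taken as its last gene or peak end.

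Overlap meant at least 1 shared base. Each of the 15 pairs of lists was set against 1000 random placements of the second list within its arms, with a one-sided permutation p in the direction seen and Benjamini-Hochberg adjustment over the pairs. The fold is the observed count over the mean of the placements, and its SD is the placement SD on the same scale. These p-values describe where intervals lie, not differences between cultures. Because the direction was taken from the data, unrelated lists pass at 0.05 in about 10% of cases: in data simulated for Su(Hw) and the first CLAMP antibody, 12.5% of 200 repeats without planted overlap passed. All 20 repeats with a planted overlap of 5% passed, and the recovered excess was 4.61%. A planted 10-point difference in kept share was recovered as 9.01 points and called in 90.5% of 200 repeats. The simulated kept shares were set far above the 2.43% kept in the data. That rate of calls therefore does not carry over to the dsRNA comparison.

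Su(Hw) peaks were divided by overlap with CP190 and Mod(mdg4), and their CLAMP shares were compared by a two-sided permutation test (10000 sets) within 10 strength classes of equal size (deciles) of the Su(Hw) fold enrichment. Only the comparison of both partners with neither was planned, and those involving Su(Hw) peaks with CP190 but not Mod(mdg4) were added. For the dsRNA comparison, mock peaks of the second antibody without an overlapping dsRNA peak were counted as lost. The kept share at sites of each insulator protein was ranked among 10000 random sets matched on deciles of mock fold enrichment and called apart outside percentiles 2.5 to 97.5, with no p. For genes, a summit within 500 bases of either end counted as bound. The 16 gene lists were histone, ribosomal protein, dosage compensation, insulator protein, Hox, heat shock, ecdysone response, hemocyte, neuronal, germline, muscle, cell cycle, Notch pathway, proteasome, transfer RNA and small nuclear RNA genes. They were tested with a two-sided Fisher exact test against all other genes, adjusted over 96 combinations of gene list and peak list. Intervals are 95% Wilson intervals, which cover counting error only.

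Groups, tests, gene lists, the naming rule and the first set of alternatives were fixed before the data were examined. The rule named the 5 peaks of each list with the largest fold enrichment, the 10 strongest Su(Hw) peaks with CP190, Mod(mdg4) and both CLAMP antibodies, and the 10 strongest mock CLAMP peaks lost and kept after dsRNA. It also named the Hox, dosage compensation and insulator protein genes and, of other lists, the 4 members with the largest fold of the first CLAMP antibody. A peak takes the name of the gene with the nearest end. Not every peak that the rule selects is named in the text. Alternatives were a larger required overlap (50% of the shorter peak), summits within 250 bases, the 50% or the 1000 peaks of each list with the highest -log10 q, and lists without the 10 sites bound in all of them. Others were circular shifts, placements matched on the distance to gene ends, unmerged rows, all sequences, regions bound in another list, other distances to genes, unmatched tests and a protein-coding background. One more was added after the data were seen: leaving out the centromere-proximal parts of the arms (2L from 22 Mb, 2R below 6 Mb, 3L from 23 Mb, 3R below 4.5 Mb and X from 21 Mb), for peaks and placements alike. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.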

Results

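The binding sites of CLAMP, a zinc-finger protein with a known part in X-chromosome dosage compensation, were mapped by ChIP-seq in Kc167 cells beside those of 3 insulator proteins. Su(Hw), Mod(mdg4) and CP190 together form the gypsy insulator complex, and the series asked how far CLAMP shares their sites across the genome. On the 6 chromosome arms the lists held 3687 Su(Hw), 1732 Mod(mdg4) and 9435 CP190 peaks. CLAMP had 5370 peaks with the first antibody and 3861 with the second. After Clamp dsRNA the second antibody gave 1653 peaks. Each list came from 2 pooled ChIP libraries, so no value below has a replicate error, and the intervals cover counting error only. The median fold enrichment was 7.14 for Su(Hw), 3.54 for Mod(mdg4), 5.59 for CP190, 2.92 and 3.64 for the CLAMP antibodies and 2.46 after dsRNA.

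CLAMP lay at a larger share of CP190 peaks than of Su(Hw) peaks. A CLAMP peak lay at 26.8% of CP190 peaks with the first antibody (2531 peaks) and at 24.3% with the second (2292 peaks). These counts were 4.16-fold (SD 0.157) and 4.34-fold (SD 0.173) the mean of random placement. Seen from CLAMP, 49.4% and 57.8% of its peaks lay at CP190. Su(Hw) peaks carried CLAMP less often, 355 (9.63%, interval 8.72 to 10.6) with the first antibody and 268 (7.27%, 6.47 to 8.15) with the second. These were 2.0-fold (SD 0.146) and 1.67-fold (SD 0.127) random placement. For Mod(mdg4) the antibodies differed: 565 peaks (32.6%) carried a peak of the first antibody and 148 (8.55%) one of the second, 6.53-fold and 2.01-fold random placement. All 6 overlaps had p = 0.001 in the one-sided permutation test, the smallest that 1000 placements can give, and an adjusted p of 0.001. Without the centromere-proximal parts of the arms, the antibodies were closer for Mod(mdg4), with 143 peaks (11.4%, 2.71-fold) and 114 (9.10%, 1.91-fold). With placements matched on the distance to gene ends, the folds were 2.24 and 2.28 for CP190 and 2.26 and 1.98 for Su(Hw), so the contrast between them nearly vanished. Within regions bound by CP190 or Mod(mdg4), CLAMP was instead rarer where Su(Hw) was present: 14.1% against 33.4% with the first antibody and 10.6% against 27.3% with the second (odds ratios 0.326 and 0.317). The same test within regions bound by Su(Hw) or CP190 gave Mod(mdg4) odds ratios of 0.744 and 0.511. Within regions bound by Su(Hw) or Mod(mdg4), CP190 had odds ratios of 0.411 and 4.72 for the first and second antibody. Without the centromere-proximal parts these were 8.45 and 8.17.

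**Figure D1:**
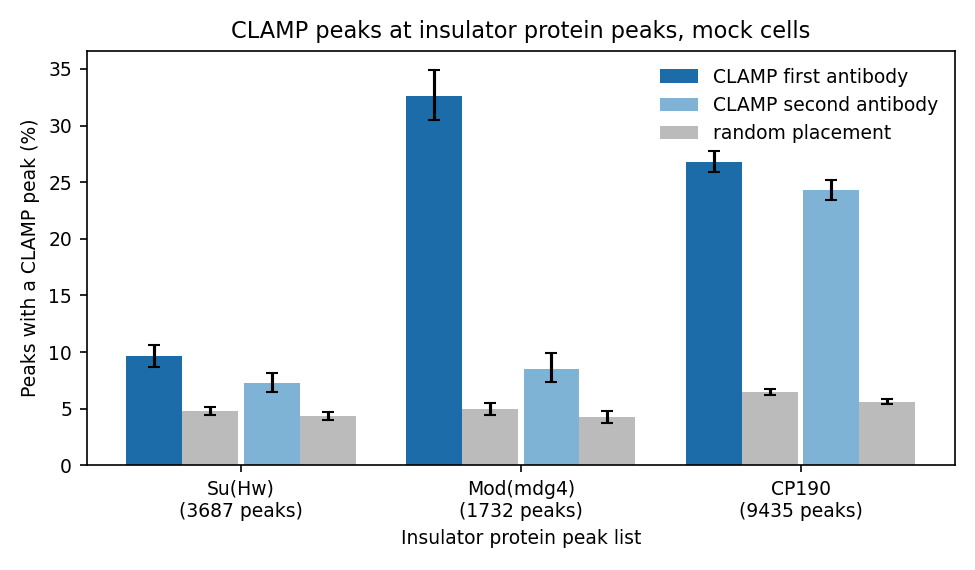
Share of the peaks of each insulator protein (x axis) that carry a CLAMP peak, in percent (y axis). Blue bars show the CLAMP antibodies with 95% Wilson intervals and grey bars the mean of 1000 random placements with its SD. The share is 26.8% and 24.3% for CP190, and 9.63% and 7.27% for Su(Hw).

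Most Mod(mdg4) peaks lay at the other insulator proteins, and most Su(Hw) peaks lay at CP190. Of the Mod(mdg4) peaks, 75.4% lay at Su(Hw) and 73.4% at CP190, and without the centromere-proximal parts these shares were 96.1% and 98.1%. CP190 lay at 76.0% of Su(Hw) peaks and Mod(mdg4) at 35.4%. Of the more numerous CP190 peaks, 28.2% lay at Su(Hw) and 12.8% at Mod(mdg4). At shared sites the summits were close, with a median distance of 26 bases between Su(Hw) and Mod(mdg4) and 30 bases between Su(Hw) and CP190. Summits of CLAMP lay farther away, at a median of 100 bases from Su(Hw) with the first antibody and 159.5 bases with the second. The 5 strongest Su(Hw) peaks were nearest to BaraA2, CG3097, Or43a (an odorant receptor gene), CG3104 and Ssk (28.2- to 29.9-fold), and all of them also had Mod(mdg4) and CP190 peaks. The strongest Mod(mdg4) peaks were nearest to Loxl1, tRNA:Arg-TCG-2-4, Pdp1, siz and CG6836 (13.3- to 16.9-fold). Those of CP190, nearest to CG6465, lncRNA:CR44415, CG14903, pan and betaTub60D, had 23.8- to 25.1-fold enrichment and no Mod(mdg4) peak, and of these only CG14903 had a Su(Hw) peak.

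CLAMP was more frequent at Su(Hw) peaks that also had CP190 than at Su(Hw) alone. Of 817 Su(Hw) peaks with neither partner, 2.94% had CLAMP with the first antibody and 1.47% with the second. With CP190 but not Mod(mdg4) (1563 peaks), the shares were 7.17% and 7.61%. At gypsy-type sites with both partners (1239 peaks), they were 12.2% (interval 10.5 to 14.1) and 10.3% (8.68 to 12.1). Su(Hw) peaks with neither partner lack CP190 by definition, and 49.4% and 57.8% of CLAMP peaks lay at CP190. Part of the difference from that class therefore follows from how the classes were made. All CP190 peaks carried CLAMP more often than gypsy-type sites, at 26.8% and 24.3%, but were wider (median 846 bases against 582). Within deciles of Su(Hw) strength, gypsy-type sites exceeded sites of Su(Hw) alone by 9.79 and 9.57 points (p = 0.0001 for each antibody in the two-sided permutation test, the smallest it can give). They exceeded Su(Hw) peaks with CP190 but not Mod(mdg4) by 5.36 and 4.24 points (p = 0.0001 and 0.0004, same test), a comparison that was not planned. The remaining 68 Su(Hw) peaks, with Mod(mdg4) and no CP190, all had a first-antibody CLAMP peak, but only 2 of them lay outside the centromere-proximal parts. With the 50% strongest peaks of each list, the excess over Su(Hw) alone was 4.43 and 3.79 points (p = 0.0001 and 0.0004). The excess over Su(Hw) peaks with CP190 but not Mod(mdg4) was gone (0.818 and -0.166 points, p = 0.575 and 1).

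**Figure D2:**
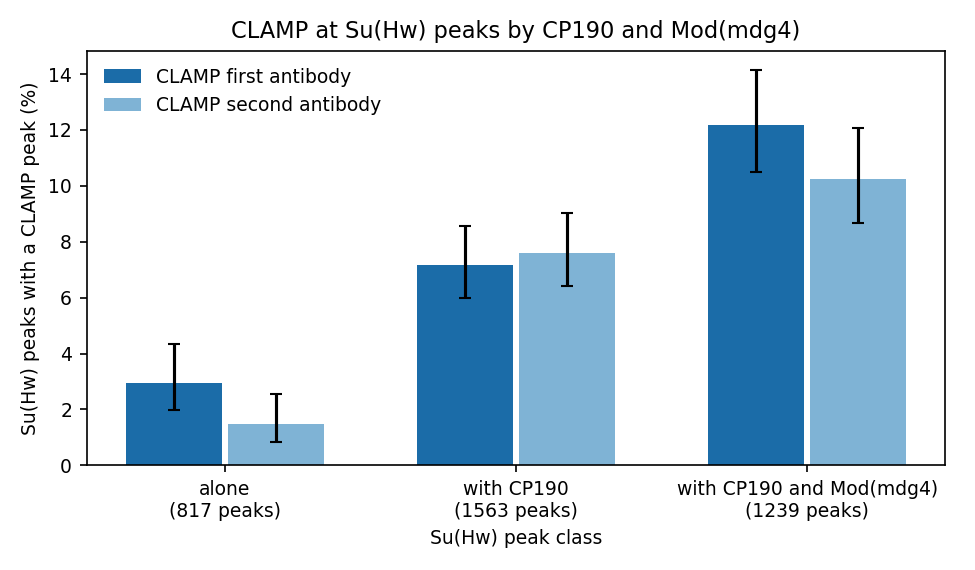
Share of Su(Hw) peaks with a CLAMP peak in percent (y axis) by the presence of CP190 and Mod(mdg4) (x axis), with 95% Wilson intervals. The share rises from 2.94% and 1.47% at Su(Hw) alone, a class that lacks CP190 by definition, to 12.2% and 10.3% with both partners. The class of 68 peaks with Mod(mdg4) and no CP190 is not drawn.

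In all, 96 Su(Hw) peaks (2.60%) had CP190, Mod(mdg4) and both CLAMP antibodies. The strongest were nearest to CG3104, Sk1, Loxl1, Muc96D, su(Hw), siz, Cln7, lncRNA:CR44503, CG6836 and boi. The gene su(Hw), which encodes Su(Hw) itself, held such a site near its end on 3R (14307701 to 14308598, dm6), with folds of 22.4 for Su(Hw), 11 for Mod(mdg4), 14.2 for CP190 and 8.44 and 9.59 for CLAMP. The peak at boi lies on X between 2469720 and 2470323. It had 20.3-fold Su(Hw) enrichment and 7.43- and 8.35-fold CLAMP enrichment, and it is shared with trol, which encodes perlecan.

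The CLAMP antibodies gave largely overlapping lists. A second-antibody peak lay at 65.3% of first-antibody peaks (64.0 to 66.5), and a first-antibody peak at 80.3% of second-antibody peaks (79.0 to 81.5), 13.5-fold random placement (p = 0.001, one-sided permutation test). Shared peaks were stronger, with a median fold of 3.91 against 2.37 for the 1865 peaks seen by the first antibody alone. Of those 1865, 46.8% lay in the centromere-proximal parts. The 5 strongest peaks of the first antibody were nearest to CG13891 and to the transcription factor genes mid, toy, H15 and Vsx1 (18.4- to 21.3-fold). Strong peaks of the second were nearest to lncRNA:bxd and to mid, disco and E5, which are likewise transcription factor genes (25.7- to 28.2-fold). With CLAMP peaks ranked by fold into 4 classes of equal size, CP190 was present at 46.8%, 40%, 44.6% and 66.1% from the weakest to the strongest class of the first antibody, and at 61.0%, 46.7%, 53.0% and 70.6% for the second, with no steady rise. The share with Su(Hw) stayed between 4.77% and 8.08% in every class of either list.

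Nearly all CLAMP peaks of the second antibody were absent from the list made after Clamp dsRNA. Of 3861 mock peaks, 3767 (97.6%, 97.0 to 98.0) had no overlapping peak after dsRNA. The Clamp gene itself carried CLAMP at its ends in mock cells (11.5-fold and 17.7-fold) and had no peak after dsRNA. The strongest lost peaks were nearest to mid, disco, E5, CG13891, asRNA:PS4 (inside Ubx), ss, asRNA:CR44018 (inside hth), PpN58A, en and mts, with mock folds of 22.7 to 28.2. The 94 kept peaks (2.43%) were strong in mock cells, with a median fold of 14.1 against 3.59 for lost peaks. Strong ones among them were nearest to lncRNA:bxd, Vsx1, unc-4, Prat2, bi, trh, oc, Lim1 and Dll. Their folds were 21.1 to 26.4 in mock cells and 1.73 to 4.13 after dsRNA. Prat2 encodes an enzyme of purine synthesis, and the other protein-coding genes among them encode transcription factors. The kept peaks were 1.53-fold random placement (p = 0.001, one-sided permutation test), and 4.75-fold without the centromere-proximal parts. No CLAMP protein or RNA level and no depth is given in the sources used here, and each condition has a single pooled list. A weaker library would also keep only the strongest peaks, so the loss is not separated from library quality. The dsRNA and mock libraries of this antibody also differ in library number (46 and 47 against 31 and 32). The loss is therefore not separated from the library set either.

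Most peaks found after dsRNA were elsewhere. Of 1653 peaks, 1534 (92.8%) had no mock peak of the same antibody, and 1247 (75.4%, 73.3 to 77.5) lay in the centromere-proximal parts, 992 of them in the first 4.5 Mb of 3R. In that part of 3R the mock lists held 16 peaks with the second antibody, 680 with the first, 349 of Mod(mdg4), 76 of Su(Hw) and 47 of CP190. Of the centromere-proximal dsRNA peaks, 72.5% overlapped a mock peak of the first CLAMP antibody and 3.69% one of the second. The 5 strongest dsRNA peaks were nearest to CG40813, bol, lncRNA:flam, Pzl and CG41562 (5.35- to 5.95-fold). lncRNA:flam is the flamenco locus, a source of small RNAs against transposons, and bol is the only one of these outside the centromere-proximal parts. Of the 406 dsRNA peaks outside the centromere-proximal parts, 187 lay in a cluster on 2L. Of the other 219, 72 (32.9%) overlapped a mock peak of the same antibody and 83 (37.9%) one of the first antibody. The dsRNA list overlapped CP190 less than random placement (0.504-fold, p = 0.001), and more than it (1.79-fold) without the centromere-proximal parts. Its overlap with Mod(mdg4) was 15.9-fold, and 3.10-fold without them. Its overlap with Su(Hw) was 2.45-fold, and 0.439-fold among the 1000 best-ranked peaks of each list.

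**Figure D3:**
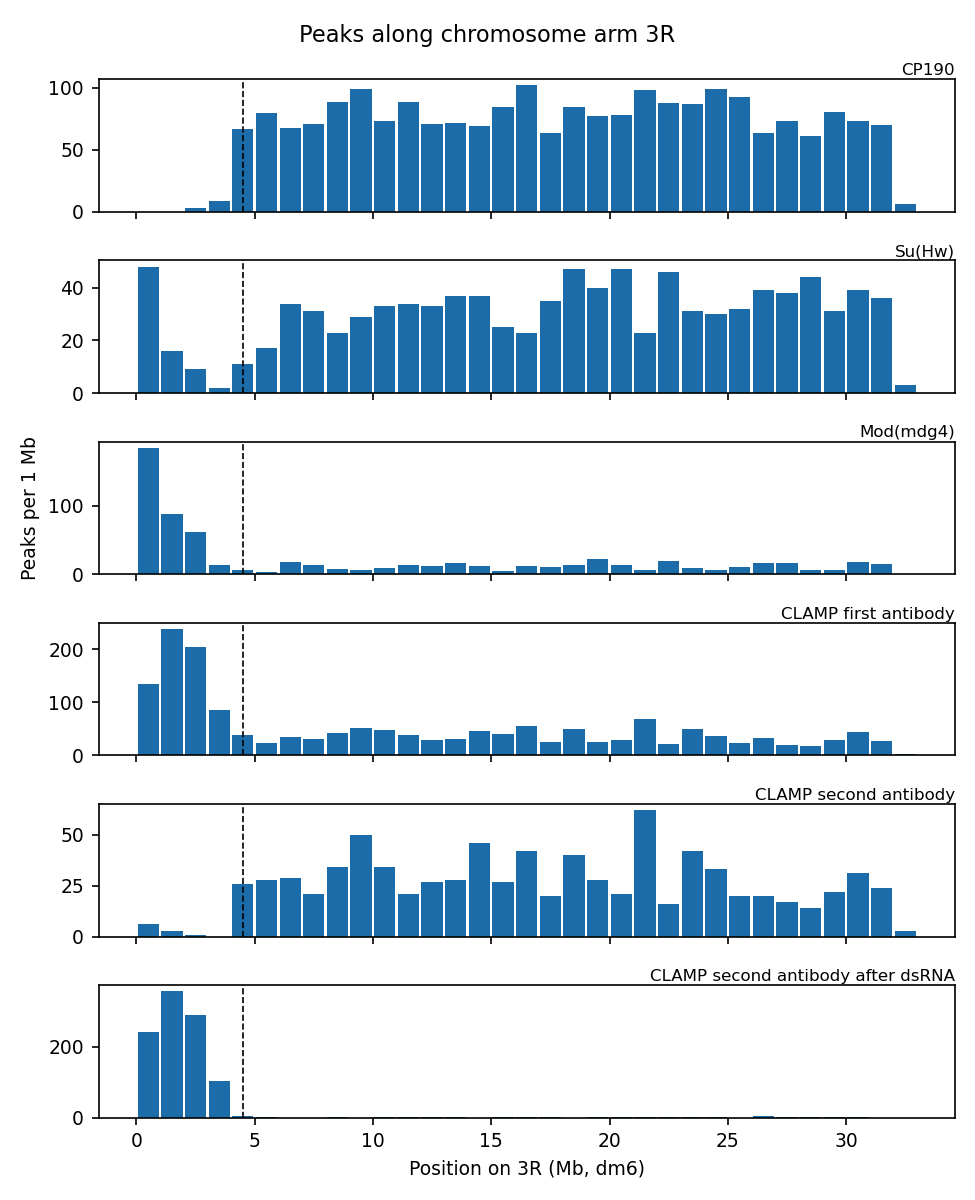
Number of peaks per 1 Mb (y axis, a separate scale per list) along arm 3R (x axis, Mb, dm6) in each list, with a dashed line at 4.5 Mb. Left of the line lie 992 peaks of the dsRNA list, 680 of the first CLAMP antibody and 349 of Mod(mdg4), against 16 of the second CLAMP antibody in mock cells.

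CLAMP peaks were kept more often where Su(Hw) or Mod(mdg4) was present. At Su(Hw), 26 of 259 mock peaks were kept (10.0%, 6.94 to 14.3) against 1.89% elsewhere, 7.36 points more than peaks of like strength (percentile 100 of the random sets). At Mod(mdg4), 26 of 139 were kept (18.7%) against 1.83%, 16.4 points more (percentile 100). At CP190, 2.60% were kept against 2.21% elsewhere, and the kept share did not stand apart from matched sets (percentile 7.58). That result was not stable, with 0.944 points (percentile 99.8) for summits within 250 bases and -0.451 points (percentile 0.645) without the sites bound in every list, both called apart. Without the centromere-proximal parts, 12 of 239 peaks at Su(Hw) were kept (5.02% against 1.62%, percentile 99.9), and 5 of 114 at Mod(mdg4) (4.39% against 1.76%, percentile 97.1, no longer called apart). Among the 1000 best-ranked peaks of each list the difference at Su(Hw) was 3.36 points and was not called apart (percentile 81.8).

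The proteins differed in where they lay relative to genes. CP190 summits fell within 500 bases of a gene end in 56.5% of peaks, 3.16-fold random placement (p = 0.001). CLAMP summits did so in 32.2% and 36.6% of peaks, 1.81-fold and 2.06-fold (p = 0.001 for each). Mod(mdg4) was at 23.4% (1.31-fold, p = 0.001). Su(Hw), at 18.0%, did not differ from random placement (1.01-fold, p = 0.413, one-sided permutation test). Su(Hw) was above random placement at 200 bases (1.10-fold, p = 0.032) and below it without the centromere-proximal parts (0.918-fold, p = 0.0149). Peaks after dsRNA avoided gene ends (5.20%, 0.287-fold, p = 0.001), but without the centromere-proximal parts they did not differ from placement (0.924-fold, p = 0.229). The X chromosome, which makes up 17.6% of the arm length, held 27.6% (26.2 to 29) of CLAMP peaks with the second antibody and 22.7% (21.6 to 23.9) with the first. It held 20.1% of Su(Hw), 19.2% of CP190 and 18.3% of Mod(mdg4) peaks, and 9.92% of peaks after dsRNA.

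CLAMP lay at the ends of Hox genes more often than at other genes. Of the 8 Hox genes, which set segment identity, 6 had a CLAMP summit within 500 bases of an end with either antibody (odds ratios 20.5 and 24.8, adjusted p = 0.00103 and 0.000501). These were lab, pb, Dfd, Scr, Antp and abd-A, with second-antibody folds from 2.32 at Antp to 18.4 at abd-A. No Hox gene had a Su(Hw) or Mod(mdg4) summit at its ends. CP190 was present at Ubx (21.8-fold) and more weakly at lab and Scr, and Abd-B had none. Of these genes only abd-A had a peak at its ends after dsRNA (2.36-fold). CLAMP also exceeded other genes at ecdysone response genes (10 and 7 of 20, adjusted p = 0.000746 and 0.0169), among them the nuclear receptor genes Hr39, Hr4 and Eip75B and the transcription factor gene Eip74EF. At heat shock genes the counts were 10 and 8 of 24 (adjusted p = 0.0030 and 0.0139), with 11.9- and 12.1-fold enrichment at Hsp68, then Hsp27, Hsp70Ba and Hsp26. Some Hox and heat shock genes lie close together, such as Dfd and Scr or Hsp26 and Hsp27. The test counted each gene separately, so such neighbours may not be independent. Notch pathway genes had 9 and 7 of 23 (adjusted p = 0.00868 and 0.0324), with nej, dx, fng and N, which encodes the receptor, as the strongest. Hemocyte genes, which mark the blood cells that Kc167 resembles, had 9 and 7 of 24 (adjusted p = 0.0109 and 0.040), led by lz, trol, zfh1 and LanA, but neither passed at 1000 bases from a gene end (adjusted p = 0.102 and 0.277).

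**Figure D4:**
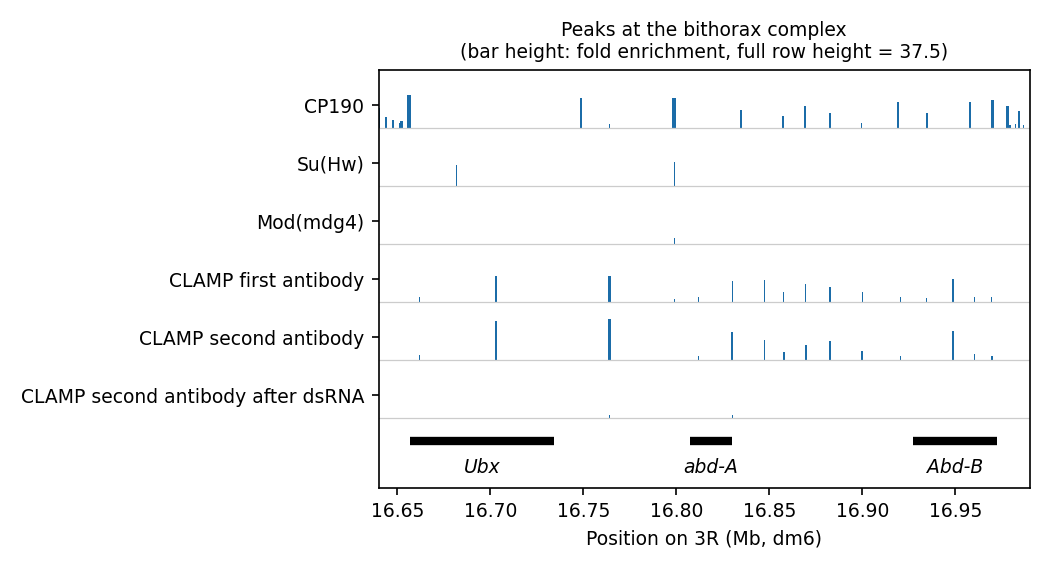
Peaks of the 6 lists along the bithorax complex on 3R (x axis, Mb, dm6), drawn at their own width with height in proportion to fold enrichment, above the extents of Ubx, abd-A and Abd-B. The tallest CLAMP peaks lie in lncRNA:bxd (17- and 26.4-fold) and inside Ubx (17- and 25.4-fold), and after dsRNA the peak in lncRNA:bxd has 2.11-fold enrichment.

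CP190 was more frequent than at other genes in 5 of the 16 gene lists. It lay at the ends of 85 of 92 ribosomal protein genes, 33 of 35 cell cycle genes, 32 of 48 proteasome genes, 22 of 30 insulator protein genes and 9 of 10 dosage compensation genes, against 44.2% to 44.4% of other genes (adjusted p = 1.03e-20, 1.41e-08, 0.0113, 0.00941 and 0.0274). CLAMP was above other genes at ribosomal protein genes (27 and 22, adjusted p = 0.000379 and 0.00245), with RpL14, RpL7-like, RpS19a and RpS28a the strongest. With the 50% best-ranked peaks of each list neither antibody passed there (odds ratios 1.14 and 0.872). CLAMP was also above other genes at cell cycle genes (11 with each antibody, adjusted p = 0.0154 and 0.00556), with dup, dap, stg and Dp the strongest. Of the dosage compensation genes, CLAMP lay at Clamp, lncRNA:roX2 (3.36- and 5.40-fold) and, with the first antibody alone, Sxl (2.0-fold). These 3 and 2 of 10 genes did not pass, against 12.8% and 10.8% of other genes. CP190 lay at all dosage compensation genes except JIL-1. Among insulator protein genes, CLAMP lay at su(Hw), psq and Chro with both antibodies, at mod(mdg4) with the first and at ZIPIC with the second. With 4 of 30 genes (13.3%) for each antibody, against 12.8% and 10.8% of other genes, CLAMP was near the share of other genes and did not pass. Small nuclear RNA genes had Su(Hw) at 12 of 32 (odds ratio 12.4, adjusted p = 2.26e-07) and Mod(mdg4) at 6 of 32 (adjusted p = 0.00261). The first CLAMP antibody lay at 9 of them, which did not pass, and the second at none; snRNA:U4:39B, snRNA:U1:95Ca, snRNA:U1:21D and snRNA:U11 had the largest first-antibody folds (2.88 to 3.23).

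Transfer RNA genes were below other genes for CP190 (86 of 295, adjusted p = 1.20e-06) and the first CLAMP antibody (23, adjusted p = 0.0312). The strongest CLAMP sites among them were tRNA:Pro-CGG-2-3, tRNA:Tyr-GTA-1-8, tRNA:Ala-TGC-2-1 and tRNA:Thr-CGT-1-2 (6.44- to 11.5-fold). These transfer RNA genes are short (tRNA:Pro-CGG-2-3 spans 18618390 to 18618461 on 3L). The windows around the ends of such a gene overlap and cover less sequence than those of a longer gene. No alternative matched genes on length, so neither deficit of transfer RNA genes is separated from short gene length. Histone genes were below other genes for CP190 (5 of 116: His3.3B, His3.3A, His4r, BigH1 and His2Av) and Su(Hw) (0). They were also below for CLAMP, with His3.3B, His4r and His2Av bound by the first antibody and His3.3B, His1:CG33801, His1:CG33864 and His2B:CG33868 by the second. How the authors treated reads from repeated genes is not given in the sources used here. The test counted each histone gene separately, so repeated copies were not independent, and no alternative changed this. No peak list passed for neuronal genes (27 genes, Syx1A, elav, dpr1 and Gad1 strongest), germline genes (21, zpg, gcl, tud and orb strongest) or muscle genes (22, with Mef2 and wupA bound by the first CLAMP antibody). Among proteasome genes CLAMP did not pass, with Rpn13 and Prosalpha7 bound with both antibodies and Rpt3 and Rpn5 with the second alone. In all, 27 of 96 combinations passed at an adjusted p of 0.05. Of these 27, 12 kept the call under every alternative that could be run: both Hox calls, the first-antibody calls for ecdysone, heat shock, Notch and histone genes, the second-antibody call for cell cycle genes, the CP190 calls for ribosomal protein, cell cycle, histone and transfer RNA genes and the Su(Hw) call for small nuclear RNA genes. The other 15 lost it under at least 1 alternative, with adjusted p from 0.0519 to 1. These are the second-antibody calls for ecdysone, heat shock, Notch and histone genes, the first-antibody calls for cell cycle and transfer RNA genes and both CLAMP calls for hemocyte and for ribosomal protein genes. They also include the CP190 calls for dosage compensation, insulator protein and proteasome genes, the Mod(mdg4) call for small nuclear RNA genes and the Su(Hw) call for histone genes.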

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

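The tests of explanations in this part were chosen after the results were seen.

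Peaks outside the 6 chromosome arms, used only in the alternative with all sequences, were more frequent after Clamp dsRNA than in mock cells. The dsRNA list had 407 such peaks of 2060 (19.8%, 18.1 to 21.5), and the mock list of the same antibody had 31 of 3892 (0.797%). Of the 407, 198 lay on sequences assigned to a chromosome without a place and 197 on unassigned ones. Among mock lists the shares were 9.70% for Mod(mdg4), 4.69% for the first CLAMP antibody, 2.69% for Su(Hw) and 0.201% for CP190.

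The same 3 lists had the largest shares in the centromere-proximal parts of the arms, where 75.4% of dsRNA peaks, 27.7% of Mod(mdg4) peaks and 18.0% of first-antibody CLAMP peaks lay, against 2.80% to 4.15% in the other lists. Loss of CLAMP as the cause in the dsRNA list stays open: 3.69% of its centromere-proximal peaks overlapped a mock peak of the same antibody, but 72.5% overlapped one of the first antibody, in cells without dsRNA. A weak enrichment of some libraries stays open. The centromere-proximal peaks had the lower median fold in 2 of the 3 lists (2.66 against 4.19 for Mod(mdg4), 2.42 against 3.25 for the first CLAMP antibody), but not after dsRNA (2.52 against 2.34). Lists without this crowding also had the lower fold there (3.27 against 7.29 for Su(Hw), 3.61 against 5.67 for CP190, 2.87 against 3.67 for the second CLAMP antibody). The comparison therefore cannot decide. A difference between sets of libraries also stays open. Both mock lists with this crowding hold a library with an early number, but so does Su(Hw), at 4.15%, and the pooled lists do not show which library a peak came from. The dsRNA list, with the largest share, came from libraries numbered 46 and 47, so an early number cannot account for it. The mock list of the same antibody came from libraries 31 and 32, so dsRNA treatment and library set cannot be told apart. How the authors treated reads that map to several places, and the copy number of these parts, are not given in the sources used here, so no explanation is singled out.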

How the results depend on the processing

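No paired analysis was possible because the lists were pooled over libraries, and for the same reason no library could be left out. Of 385 values under 17 alternatives, 320 kept their direction and side of the threshold or moved less than their interval. Leaving out the centromere-proximal parts was added after the data were seen; the motif alternatives were not run for lack of a genome sequence, and unmerged rows differ from merged ones only by the random draw. Unknown depth limits every absent peak. The overlaps of CLAMP with Su(Hw) stayed above random placement under every alternative placement or list, from 1.39-fold to 3.35-fold, and those with CP190 from 2.24-fold to 9.12-fold. Gypsy-type sites exceeded Su(Hw) alone by 3.79 to 9.45 points. The cause of the changes below was not tested.

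Within regions bound in another list, odds ratios fell below 1 for Su(Hw) with the mock CLAMP lists (0.326 and 0.317) and Mod(mdg4) with them (0.744 and 0.511). CP190 with the first antibody gave 0.411, but 8.45 without centromere-proximal parts. Su(Hw) with dsRNA CLAMP gave 0.772, not past the threshold (adjusted p = 0.0582, two-sided Fisher exact test), and 1.19 without those parts. Mock with dsRNA CLAMP gave 1.06, not past the threshold, and 12.6 without those parts. Su(Hw) with dsRNA CLAMP turned to 0.982-fold with the 50% best-ranked peaks and 0.439-fold with 1000. CP190 with dsRNA CLAMP turned to 1.07-fold for summits within 250 bases and 1.79-fold without centromere-proximal parts, and 0.662-fold under circular shifts missed the threshold. Near gene ends, Su(Hw) was 1.10-fold at 200 bases, now past it, and turned to 0.978-fold at 1000 bases and 0.918-fold without centromere-proximal parts, where the dsRNA list was 0.924-fold and no longer past it.

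Antibody agreement, 65.3% and 80.3%, moved to 54.0% and 75.1% (summits), 74.2% and 93.2% (50% best-ranked) and 87.8% and 83.5% (1000 peaks). For the first antibody it was 63.8% with 50% of the shorter peak covered and 77.5% without centromere-proximal parts. The lost share, 97.6%, moved to 98.0% (summits), 94.7% (1000 peaks), 98.2% (without centromere-proximal parts) and 97.0% (peaks of both antibodies). The share of dsRNA peaks absent from mock, 92.8%, moved to 95.3% (summits), 91.3% (50% best-ranked), 94.3% (without sites in every list) and 82.0% (without centromere-proximal parts). The 82.0% rests on 406 dsRNA peaks, of which 187 lay in the cluster on 2L.

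The kept share at Su(Hw) fell to 3.36 points (1000 peaks) and at Mod(mdg4) to 2.62 (without centromere-proximal parts), neither called apart. At CP190, -0.274 points became 0.944 (summits, called apart), -0.451 (without sites in every list, called apart), 0.103 (without centromere-proximal parts) and 0.165 (unmatched). The 27 gene list combinations became 53 with any overlap of peak and gene and 17 with the 50% best-ranked peaks, where ribosomal protein genes with the second CLAMP antibody turned to an odds ratio of 0.872.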

Other observations

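The tests on the distance to gene ends, on CP190 and on centromere-proximal peaks in this part were chosen after the results they measure were seen; the test on transcription factor genes was written before its result. The genes named in the first paragraph were chosen after their values were seen.

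Many of the strongest CLAMP peaks lay beside genes for developmental transcription factors, which raised the hypothesis that such genes carry CLAMP at their ends more often than other protein-coding genes. A list of 70 such genes was written without the genes of the fixed lists and without those named for the strongest peaks; 69 were in the gene table. The first antibody lay at the ends of 46 of them (66.7%, 54.9 to 76.6) against 13.6% of 13842 other genes, an odds ratio of 12.7 (p = 8.43e-24, two-sided Fisher exact test, adjusted p = 5.06e-23 over 6 lists). The second antibody lay at 43 (62.3%, odds ratio 12.7). The largest first-antibody folds were at eyg (16.4), pnr (14.9), caup (14.7), lbe (13.9) and tup (13.2), with 19.3- to 21.3-fold enrichment for the second. CP190 was rarer there than at other genes, with 15 genes (21.7% against 51.5%, odds ratio 0.261, adjusted p = 1.31e-06). Su(Hw) lay at 5 (eyg, btd, dac, salr and eya) and Mod(mdg4) at 0, neither past the threshold, and eyg and cad had a peak after dsRNA. Some of these genes are neighbours that can share a peak, so they are not independent. The result is consistent with the hypothesis, which arose from other peaks of the same lists.

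A second cluster of dsRNA peaks lay on 2L, with 187 summits from 14730332 to 18387343. The window of 4 Mb around them held, in the mock lists, 104 first-antibody and 77 second-antibody CLAMP, 200 CP190, 118 Su(Hw) and 33 Mod(mdg4) peaks. Each mock CLAMP list overlapped only 1 of the 187. Copy number, input signal and the treatment of repeated reads in this part are not given in the sources used here, and no test of a cause was run.

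CLAMP at Su(Hw) peaks exceeded random placement. Nearness to either gene end does not account for this. Su(Hw) summits lay within 500 bases of an end about as often as placement gives (1.01-fold), and 1.10-fold within 200 bases. Placements matched on the distance to gene ends accordingly did not raise the mean overlap, and the fold was 2.26 for the first antibody and 1.98 for the second. Nearness to transcription starts was not tested, because gene strand was not available. The presence of CP190 as a cause stays open. Within regions bound by CP190 or Mod(mdg4), CLAMP was rarer where Su(Hw) was present (odds ratios 0.326 and 0.317), so no excess was seen among such regions. Su(Hw) peaks with neither CP190 nor Mod(mdg4) were set against CLAMP peaks outside both, with placements held outside both as well. They had CLAMP at 1.36 times random placement with the first antibody and 0.721 times with the second (22 and 10 peaks, p = 0.0799 and 0.169, one-sided permutation test), so the antibodies went opposite ways and neither passed.

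CLAMP peaks were kept after dsRNA more often at Su(Hw) and Mod(mdg4). Centromere-proximal peaks are not the whole cause at Su(Hw), where the kept share without them was still at percentile 99.855 of sets of like strength. The difference was smaller there, 2.87 points instead of 7.36, and rests on 12 kept peaks. For Mod(mdg4), with 5 kept peaks and percentile 97.13, the pattern cannot be told apart from an effect of the centromere-proximal peaks.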
